A study of Mus musculus with 12 samples.

How the data were processed

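Poly(A) RNA of mouse splenic B cells was sequenced in 12 libraries, per the labels. The deposited values used here are raw counts per Ensembl gene, with 1 column for each library, spread over 3 tables. Per the submitters' processing notes, reads were checked with FastQC 0.10.1, trimmed with cutadapt 1.9.1, aligned to GRCm39 with HISAT2 2.2.1 and counted with HTSeq 0.6.1. The strand setting and the annotation release are not given in the sources used here, so values of overlapping or antisense genes are uncertain. The deposited tables of untreated, stimulated and additional WT cells held counts for 55359, 56691 and 55401 genes, of which 55349 were common to the first pair of tables and 52330 to all. Gene coordinates in the table of the additional WT cells are of an older build than GRCm39, which the labels give. Exonic gene lengths and 12 columns of FPKM values per sample were also held and were not used here. Splicing was not analysed here, since the counts are of whole genes. Additional WT libraries were kept apart, since their titles set them apart from the numbered ones, and entered only the alternative that counts them as WT. Of the stimulated WT columns 1 carries the number 3, while the labels number these libraries 1 and 2, so it was used as WT without a number and is called the unnumbered WT library.

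Comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and two-sided test, TMM scaling, genes kept by filterByExpr with a minimum count of 10 and a minimum total of 15), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. DKO was compared with WT in the 6 untreated libraries and in the 4 stimulated libraries in separate fits. The interaction, and stimulated against untreated cells of each genotype, were tested in 1 fit over the 10 libraries of 4 groups, with 1 mean per group and genes joined by identifier. Log2 fold changes are DKO over WT, or stimulated over untreated. They are given ± a standard error worked out as the absolute change over the square root of the F statistic. For genes with few counts in a group it can be smaller than the counting error. CPM values were scaled with the TMM factors of each fit, except those of the targeted genes, Gm10052, the Nfe2 libraries, Meiosin in stimulated cells, the ribosomal protein genes and pseudogenes, the additional libraries and the genes of the last part of the text, which were divided by the plain total.

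The 35 gene lists hold pathways, B cell stages and markers of other cell types. Each list with 5 or more tested genes was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over the lists. It was tested again with a correlation estimated from the data, and with fry. The test with an estimated correlation has only the residual degrees of freedom of a fit. These were 4 for untreated cells, 2 for stimulated cells and 6 for the joint fit. It thus has little power, and a list that does not pass it is not shown to be unchanged. In untreated cells the estimate was 0.141 for B1 and age-associated genes and 0.288 for transitional genes, above the preset 0.01. It was 0.00714 for SR proteins and -0.0329 for follicular genes, below the preset. Where members correlate more than the preset, the camera p-values at the preset can be too small. Members past the threshold were counted over all genes and again with p-values adjusted over the list alone. Random lists of the closing part were matched on the GC content and length of each gene's longest GENCODE M21 transcript. The overlap of calls was compared with the product of both counts over the number of genes tested in both comparisons. Genes were named by a fixed rule. It took both targeted genes, the 10 largest changes in each direction (5 for the interaction) among genes past the threshold with a mean of 5 CPM or more in a group and, for DKO against WT, no overlap between groups, and the members of each list with the smallest p. Genes without a name and immunoglobulin segments were left out, and some genes that the rule names are not reported here.

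The alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, a stricter filter (at least 1 CPM in every library of a group), leaving out each library, the replicate number as a block, immunoglobulin genes left out, a minimum log2 fold change of 1, a single fit over 10 libraries and the additional WT libraries counted as WT. A term for sex, fits without the 2 libraries that read as female and list tests with the additional WT libraries were added after the data were seen. The pipeline was tested on simulated counts with 200 changed genes in each of 5 draws. In the data 2638 genes passed in untreated and 1625 in stimulated cells, so the shares that follow need not hold there. The simulated groups also had the same spread for each gene, while the stimulated DKO libraries differed more from each other than the stimulated WT libraries did. For the untreated comparison (13325 genes) the pipeline recovered 39.6%, 77.5% and 94.6% of genes changed 1.5, 2 and 4 times, and 5.44% of its calls were false. For the stimulated comparison (14136 genes) it recovered 7.85%, 51.4% and 85.1%, with 12.8% false calls. For the interaction (14582 genes) it recovered 3.64%, 25.3% and 75.5%, with 6.93% false calls. For stimulated against untreated cells it recovered 19.0%, 59.5% and 87.2% in WT (14605 genes, 5.92% false) and 14.4%, 56.2% and 79.1% in DKO cells (14595 genes, 7.31% false). The coefficient of biological variation was 13.2% in the untreated fit, 17.4% in the stimulated fit and 15.3% in the joint fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.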

Results

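RNA sequencing was carried out on B cells purified from mouse spleen, after beads had taken out cells carrying the surface protein CD43. The double knockout (DKO) cells had lost both Hnrnpa1 and Hnrnpa2b1 by Cre-loxP recombination. Their products, hnRNP A1 and hnRNP A2B1, are nuclear RNA-binding proteins that act in splicing and RNA transport. The series asks how these proteins act in the germinal centre B cell response. The 12 libraries formed 5 groups. There were 3 wild-type (WT) and 3 DKO libraries of untreated cells, and 2 WT and 2 DKO libraries of cells cultured for 48 h with 1 µg/mL anti-CD40 and 10 µg/mL anti-IgM. A further 2 libraries came from additional WT untreated cells. Antibodies against CD40 and IgM stand in for T cell help and antigen. Counts assigned to genes ranged from 15090953 to 21731893 per library. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples.

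Transcripts of both targeted genes were reduced in all 5 DKO libraries, and some counts remained. Hnrnpa1 (ENSMUSG00000046434; GRCm39 chromosome 15, 103148859 to 103155119, plus strand) had 726 ± 12.9 CPM (counts scaled to the library total, mean ± SD, n = 3) in untreated WT cells and 125 ± 65.2 (n = 3) in untreated DKO cells. Hnrnpa2b1 (ENSMUSG00000004980; chromosome 6, 51437912 to 51446874, minus strand) had 1920 ± 123 and 447 ± 152 CPM in the same groups. In the stimulated cells Hnrnpa1 had 1733 ± 7.11 CPM in WT and 245 ± 9.93 in DKO, and Hnrnpa2b1 had 1833 ± 13.1 and 375 ± 63.8 (n = 2 each). The untreated DKO library numbered 2 kept the most, with 27.4% of the WT mean for Hnrnpa1 and 32.3% for Hnrnpa2b1, against 10.6% and 17.4% in number 1 and 13.6% and 20.2% in number 3. The stimulated DKO libraries kept 14.6% and 13.8% of Hnrnpa1 and 18.0% and 22.9% of Hnrnpa2b1. On the log2 scale Hnrnpa1 changed by -2.46 ± 0.30 (± SE from the F statistic) in untreated cells (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00217). In stimulated cells it changed by -2.72 ± 0.20 (adjusted p = 0.000321). Hnrnpa2b1 changed by -2.03 ± 0.20 (adjusted p = 0.00142) and -2.19 ± 0.20 (adjusted p = 0.00115). The difference between the changes in stimulated and untreated cells did not pass, with interaction terms of -0.22 ± 0.40 for Hnrnpa1 (edgeR adjusted p = 0.856) and -0.13 ± 0.29 for Hnrnpa2b1 (edgeR adjusted p = 0.879). Counts over whole genes can include reads from exons outside the deleted parts and from other cells that kept the genes. Gm10052 (chromosome 9, 123518298 to 123519257) was taken as a copy of the Hnrnpa1 transcript, without a sequence comparison here, and was chosen after its values were seen. It had 475 ± 52.5 CPM in untreated WT and 74.4 ± 43.5 in untreated DKO cells. In stimulated WT and DKO cells it had 110 ± 2.98 and 14.5 ± 0.357 CPM. Reads assigned to either gene are thus uncertain, and so is the difference in Hnrnpa1 between untreated and stimulated WT cells.

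**Figure D1:**
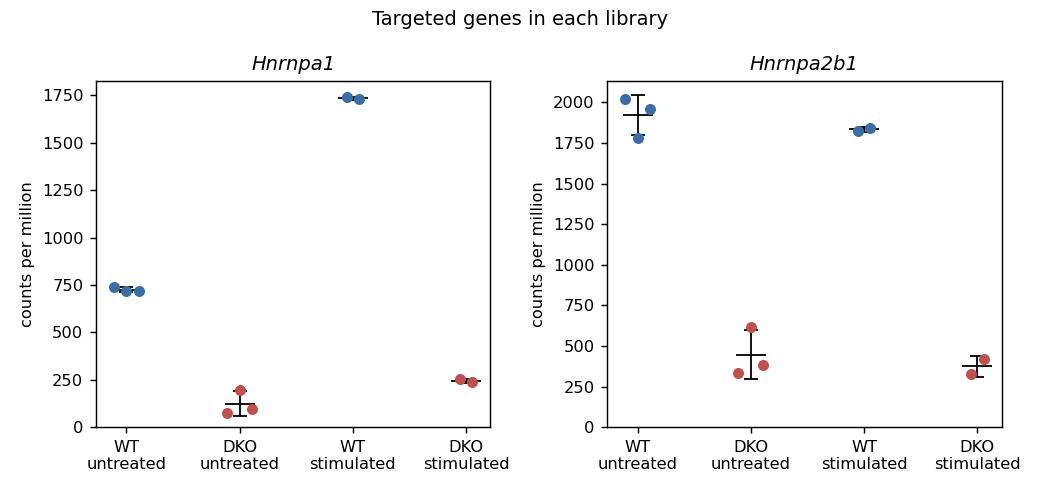
CPM of Hnrnpa1 and Hnrnpa2b1 in each library of the 4 groups (points), with the mean (wide line) and SD (bars); WT libraries are blue and DKO libraries red. The 5 DKO libraries lie between 76.7 and 252 CPM for Hnrnpa1, below each of the 5 WT libraries, whose lowest value is 718.

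The first comparison asked which transcripts differed between DKO and WT B cells labelled untreated. Of 29 gene lists tested, 15 passed camera, 4 with higher and 11 with lower values in DKO cells, though in most lists only part of the genes passed. The higher lists were ribosomal proteins, ribosome biogenesis, oxidative phosphorylation and the response to NF-kB and CD40. Among the lower lists were markers of marginal zone, B1, plasma and immature B cells, B cell receptor signalling, antigen presentation and mitosis. None of the 15 stayed past the threshold in a second test of the lists, where the lowest value was adjusted p = 0.298 with an estimated correlation. With fry, 8 of the 15 were among the 9 lists that passed. Nfe2, which encodes a transcription factor subunit of red cell and platelet precursors, and the meiotic genes Meiosin and Stag3 were higher in DKO cells. In all, 2638 of 13561 tested genes passed an adjusted p of 0.05, 1195 higher and 1443 lower, and 196 of the former and 427 of the latter changed by at least 1 on the log2 scale. The 3 DKO and 3 WT values did not overlap in 2630 of the 2638, and in 39.2% of all tested genes, where chance gives 10%.

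Among the cytosolic ribosomal proteins, 37 of the 47 tested genes rose and none fell (40 rose adjusted over the list alone), with a median log2 fold change of 0.41. Rplp2 rose by 0.65 ± 0.07, Rpl37 by 0.65 ± 0.08, Rps15 by 0.56 ± 0.07 and Rplp0 by 0.53 ± 0.07. The list stood above other genes (camera adjusted p = 1.19e-23; adjusted p = 0.298 with an estimated correlation). In the same libraries the summed CPM of 323 ribosomal protein pseudogenes was 6418 ± 319 in WT and 8113 ± 276 in DKO cells, and the 10 most abundant genes took 5.41% to 5.61% of counts in WT and 7.02% to 7.05% in DKO libraries. Of the MYC targets and ribosome biogenesis genes, 12 of 35 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 1.02e-05; adjusted p = 0.548 with an estimated correlation). Polr1c, a subunit of RNA polymerases I and III, rose by 0.55 ± 0.09 and Npm1, the nucleolar protein nucleophosmin, by 0.43 ± 0.07. In oxidative phosphorylation 14 of 36 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000116; adjusted p = 0.596 with an estimated correlation). The respiratory chain subunits Cox6c and Cyc1 rose by 0.55 ± 0.10 and 0.41 ± 0.07, while Ndufa10 changed by -0.45 ± 0.07. Of the NF-kB and CD40 response genes, 10 of 31 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.00283; adjusted p = 0.298 with an estimated correlation). The chemokine gene Ccl22 rose by 1.78 ± 0.21, Ebi3, a subunit of interleukins 27 and 35, by 0.79 ± 0.10, the survival gene Bcl2l1 by 0.77 ± 0.07 and the NF-kB inhibitor Nfkbia by 0.44 ± 0.06.

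Several lists of B cell subset markers passed camera on the lower side. Of the marginal zone genes 6 of 16 fell and none rose (10 fell adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.000116, and adjusted p = 0.298 with an estimated correlation). S1pr3, the sphingosine phosphate receptor of marginal zone cells, changed by -1.98 ± 0.28, Myof by -1.53 ± 0.27, Plac8 by -1.46 ± 0.31 and Dtx1, a regulator of Notch signalling, by -1.02 ± 0.11. In the B1 and age-associated list 7 of 15 fell and none rose (the same numbers adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.000366, and adjusted p = 0.298 with an estimated correlation). Ctla4, an inhibitory receptor gene, changed by -1.58 ± 0.21, Ahnak by -1.44 ± 0.19, Bhlhe41, a transcription factor of B1 cells, by -1.07 ± 0.18 and Zeb2 by -0.98 ± 0.16. Of the plasma cell genes 6 of 15 fell (7 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.00283, and adjusted p = 0.298 with an estimated correlation). Creb3l2 changed by -1.28 ± 0.20 and Xbp1, which drives secretory expansion, by -0.60 ± 0.10. The unfolded protein response, which shares Xbp1 and Edem1 with that list, had 8 of 26 lower (10 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.00208, and adjusted p = 0.298 with an estimated correlation). Calr, an endoplasmic reticulum chaperone, changed by -0.42 ± 0.08. Transitional and immature B cell genes had 3 of 9 lower (4 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.00443, and adjusted p = 0.440 with an estimated correlation). These were Vpreb3 with -1.75 ± 0.40, Cd93 with -1.26 ± 0.16 and Ms4a4c with -1.02 ± 0.17.

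B cell receptor signalling and identity genes had 9 of 30 lower and none higher (16 lower and 1 higher adjusted over the list alone), with a median of -0.23 (camera adjusted p = 2.43e-05; adjusted p = 0.400 with an estimated correlation). The inhibitory receptor gene Fcgr2b changed by -0.91 ± 0.11, the adaptor gene Bank1 by -0.77 ± 0.08 and the kinase gene Btk by -0.40 ± 0.07. Antigen presentation had 7 of 21 lower and 1 higher (7 and 1 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.00219; adjusted p = 0.637 with an estimated correlation). The class II gene H2-Aa changed by -0.76 ± 0.12 and its regulator Ciita by -0.61 ± 0.13. Ifi30, a thiol reductase of the antigen-processing compartment, rose by 0.78 ± 0.17. Mitosis genes had 8 of 32 lower (11 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 2.43e-05; adjusted p = 0.637 with an estimated correlation). The mitotic kinase gene Plk1 changed by -1.41 ± 0.32 and the cyclin gene Ccnb1 by -1.09 ± 0.25. Interferon-stimulated genes had 6 of 38 lower (6 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.00413, and adjusted p = 0.731 with an estimated correlation). The RNA sensor genes Ifih1 and Ddx58 changed by -0.98 ± 0.18 and -0.51 ± 0.11. Chemokine, cytokine and homing receptors had 9 of 26 lower and 1 higher (10 and 2 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0279, and adjusted p = 0.298 with an estimated correlation). The egress receptor gene S1pr1 changed by -1.44 ± 0.23, Il10ra by -0.77 ± 0.15, Il4ra by -0.61 ± 0.10 and Cxcr4 by -0.47 ± 0.08. Cholesterol synthesis had 5 of 20 lower (6 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0332, and adjusted p = 0.613 with an estimated correlation). Mvk changed by -0.46 ± 0.11 and Hmgcs1 by -0.33 ± 0.08.

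Some of these calls were lost on leaving out 1 library. The call for interferon-stimulated genes was lost without WT number 1 (camera adjusted p = 0.0891) or DKO number 1 (0.105), and that for antigen presentation without WT number 1 (0.0506). The call for homing receptors was lost without WT number 1 (0.0580) or DKO number 1 (0.126), and that for cholesterol synthesis without WT number 2 (0.0661) or DKO number 1 (0.208). Both were also lost in the 4 male libraries, a subset chosen after the data were seen (camera adjusted p = 0.0933 and 0.233). With the additional WT libraries counted as WT, also tried after the data were seen, these list calls were lost: NF-kB and CD40 response, unfolded protein response, antigen presentation, homing receptors, interferon-stimulated genes and cholesterol synthesis. Of the 93 genes named for untreated cells, 19 lost the call on leaving out 1 library, 17 of them without WT number 3 and 17 without DKO number 3. These were Cbx5, Ccnb1, Ciita, Ddx58, Egr1, Gp1ba, H1f0, Hmgcs1, Hmox1, Hnrnpll, Ifi30, Mvk, Plac8, Plk1, Rbm5, Rn18s-rs5, Smug1, Vpreb3 and Zbtb46. Both mitosis genes named above are thus among them, Plk1 without WT number 3 (edgeR adjusted p = 0.0623) or DKO number 3 (0.0612).

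The other 14 tested lists did not pass camera, whose adjusted p closes each bracket that follows. Among the other hnRNP genes 6 of 26 rose and 4 fell (the same numbers adjusted over the list alone, 0.857). The close paralogue Hnrnpa3 changed by -0.91 ± 0.09 (edgeR adjusted p = 0.00142) and Hnrnpd by -0.45 ± 0.08, while Hnrnpll, a splicing regulator of lymphocytes, rose by 1.19 ± 0.24 and Hnrnpab by 0.43 ± 0.07. SR proteins and splicing regulators had 1 of 29 higher and 4 lower (1 and 4 adjusted over the list alone, 0.824). Pspc1 stood at 0.45 ± 0.07 and Rbm5 at -0.32 ± 0.07. Follicular B cell genes had 2 of 15 higher and 4 lower (2 and 5 adjusted over the list alone, 0.0962). Klf2, which restrains the exit from quiescence, stood at -1.11 ± 0.19 and the IgE receptor gene Fcer2a at 0.90 ± 0.17. Germinal centre genes had 1 of 18 higher and 4 lower (1 and 4 adjusted over the list alone, 0.2885). Basp1 stood at 1.31 ± 0.15, Cd38 at -0.91 ± 0.17 and Pou2af1, a coactivator needed for germinal centres, at -0.42 ± 0.07. Apoptosis regulators had 3 of 22 higher and 5 lower (3 and 6 adjusted over the list alone, 0.286). The pro-apoptotic genes Bmf and Bcl2l11 stood at -1.71 ± 0.21 and -0.62 ± 0.09. Targets of p53 had 5 of 25 higher and 2 lower (5 and 2 adjusted over the list alone, median 0.20, 0.160). Phlda3 stood at 1.11 ± 0.19, Psrc1 at 0.94 ± 0.16, Zmat3 at 0.79 ± 0.14 and Ephx1 at -1.28 ± 0.15. Immediate early genes had 6 of 23 lower (6 lower and 1 higher adjusted over the list alone, 0.286). The transcription factor gene Egr1 stood at -0.67 ± 0.15. Immunoglobulin constant genes had 2 of 11 higher and 2 lower (2 and 3 adjusted over the list alone, 0.348). Ighm, the constant gene of IgM, stood at -0.67 ± 0.10. DNA replication had 2 of 34 higher and 1 lower (0.195) and glycolysis and hypoxia 1 of 25 higher and 2 lower (0.2885), with none of either adjusted over the list alone.

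Lists for other cell types held few tested genes. T cell genes had 1 of 8 lower, Cd2 with -1.79 ± 0.15 (1 adjusted over the list alone, camera adjusted p = 0.145). Dendritic cell genes had 1 of 8 higher, the transcription factor gene Zbtb46 with 0.40 ± 0.09 (1 adjusted over the list alone, camera adjusted p = 0.843). Monocyte and macrophage genes had 2 of 12 lower, Adgre1 with -1.12 ± 0.17 and Hmox1 with -0.45 ± 0.11 (2 adjusted over the list alone, camera adjusted p = 0.857). The list's median was 0.07 and its mean 0.12, while camera gave the direction down. None of 5 erythroid genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.860). With under 5 tested genes and no list test, Il2rb (-1.12 ± 0.23) was lower among 4 natural killer cell genes, Gp1ba (1.71 ± 0.43) higher among 2 platelet genes and Pecam1 (-1.11 ± 0.15) lower among 3 stromal and endothelial genes. H1f0 was lower among 2 genes of the histone list. Adjusted over the list alone, 1 natural killer cell gene was higher and 2 lower, and the numbers for the other 3 lists did not change. No neutrophil gene was tested.

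Among single genes, Nfe2 rose from 7, 6 and 8 counts in the WT libraries to 1938, 1818 and 2003 in the DKO libraries, a log2 change of 8.36 ± 0.14 (edgeR adjusted p = 5.19e-09). It lies on chromosome 15 from 103156639 to 103166830 on the minus strand, tail to tail with Hnrnpa1, whose annotated 3′ end is 1.52 kb away. The strand setting of the counting was not given, so the counts there can hold reads from either strand. Of the 6 genes tested within 100 kb of Hnrnpa1, Nfe2 among them and named after their values were seen, Cbx5 (0.42 ± 0.09) and Smug1 (0.42 ± 0.11) were also higher and Zfp385a lower (-1.23 ± 0.22), and none of the 2 near Hnrnpa2b1 passed. Meiosin, which starts meiosis, rose from 0.0940 to 10.4 CPM (6.74 ± 0.49), and Stag3, a meiotic cohesin subunit, rose by 2.30 ± 0.34. The growth hormone gene Gh rose by 3.02 ± 0.27, the noncoding RNA Lncpint by 2.68 ± 0.37, the metallothionein gene Mt2 by 2.67 ± 0.48, Rskr by 2.13 ± 0.31, the hyaluronan synthase gene Has3 by 2.12 ± 0.22 and Glt28d2 by 2.09 ± 0.26. Rn18s-rs5, a copy of 18S ribosomal RNA, went from 623 ± 260 to 2422 ± 1826 CPM (1.96 ± 0.48, edgeR adjusted p = 0.0236), a call lost without WT number 1, WT number 3 or DKO number 3. On the lower side, Il10, the gene of an anti-inflammatory cytokine of B cells, went from 5.19 to 0.690 CPM (-2.89 ± 0.54). The transcription factor gene Etv5 (-2.11 ± 0.24), Lbhd1 (-2.04 ± 0.20), Pdzd2 (-1.94 ± 0.36), the acetylcholine receptor subunit gene Chrnb1 (-1.81 ± 0.19) and Pafah2 (-1.79 ± 0.25) also fell.

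**Figure D2:**
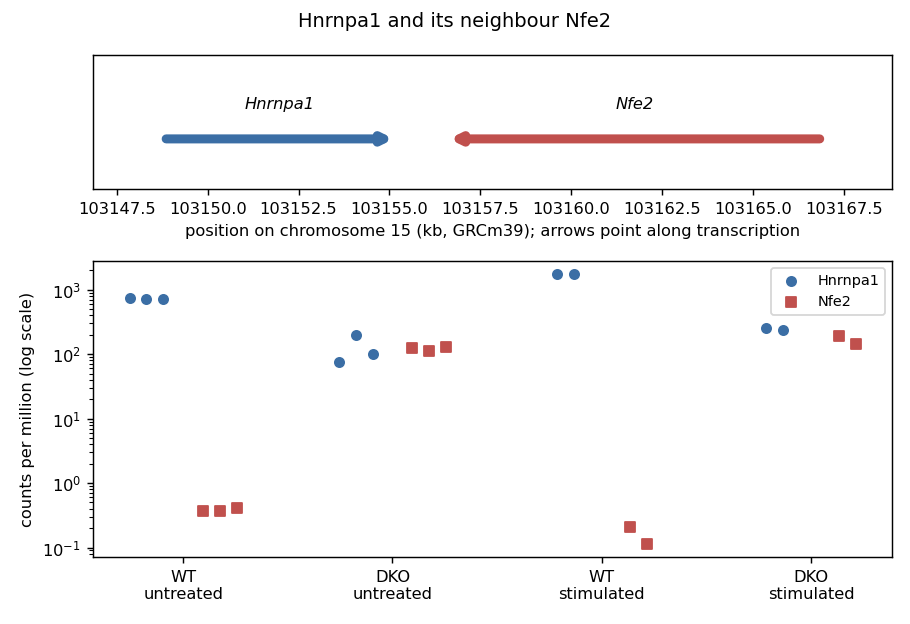
Top, positions and directions of Hnrnpa1 and Nfe2 on chromosome 15 (GRCm39, kb); bottom, CPM of each gene in every library of the 4 groups, on a log scale. Nfe2 lies at 0.365 to 0.414 CPM in the untreated WT libraries and at 113 to 130 CPM in the untreated DKO libraries.

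The number of genes past the threshold fell to 1704 without WT number 1, 923 without WT number 3 and 1146 without DKO number 3. It was 319 with the additional WT libraries counted as WT replicates, and 4392 with the sex of the animal, read from Xist and Ddx3y after the data were seen, as a term. With the additional WT libraries 55 of 92 named genes lost the call, among them Rplp2 (0.03), Polr1c (0.09) and Ebi3 (0.19). Another 5 turned sign, among them Mt2 (-0.91) and Hnrnpll (-0.0007).

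The same question was then asked of cells stimulated for 48 h, with 2 libraries on each side. Of 30 gene lists tested, 15 passed camera, 9 with higher and 6 with lower values in DKO cells. Targets of the tumour suppressor p53 were among the higher lists, with Cdkn1a, which encodes an inhibitor of cyclin-dependent kinases, at 22.4 ± 7.15 CPM against 1.83 ± 0.56. Ribosomal proteins, MYC targets and the NF-kB and CD40 response were again among the higher lists, and B cell receptor and antigen presentation genes among the lower. None of the 15 stayed past the threshold in the second test, where the lowest value was adjusted p = 0.612 with an estimated correlation. That test has little power at 2 residual degrees of freedom. With fry, 1 of the 15 was among the 4 lists that passed. Meiosin and Stag3 were again higher. Of 14430 tested genes, 1625 passed an adjusted p of 0.05, 734 higher and 891 lower, with 371 and 524 changed by at least 1 on the log2 scale. The groups did not overlap in any of the 1625, and in 61.5% of all tested genes, where chance gives 33.3%. Across genes the DKO libraries differed more from each other than the WT libraries did. The chi-square per degree of freedom was 49.5 for the DKO pair and 9.66 for the WT pair.

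Of the 25 tested p53 targets 10 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 3.99e-10; adjusted p = 0.612 with an estimated correlation). Phlda3, an inhibitor of AKT signalling, rose by 4.14 ± 0.41, Cdkn1a by 3.62 ± 0.32 (edgeR adjusted p = 0.00115), Psrc1 by 2.47 ± 0.23 and Zmat3, which encodes an RNA-binding protein, by 1.61 ± 0.19. Of the ribosomal proteins 18 of 47 rose (all 47 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 2.75e-18; adjusted p = 0.612 with an estimated correlation), among them Rps27 with 1.04 ± 0.21 and Rps20 with 1.00 ± 0.22. The summed CPM of these 47 genes was 83292 in DKO number 1 and 62110 in DKO number 2, and mitochondrial genes took 4.68% and 3.74% of counts there against 3.60% and 3.16% in the WT libraries. MYC targets and ribosome biogenesis had 16 of 35 higher (29 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 7.87e-13; adjusted p = 0.612 with an estimated correlation). Myc itself rose by 1.08 ± 0.19, Nop56 by 1.10 ± 0.20, and the polymerase subunit genes Polr1c by 1.01 ± 0.19 and Polr1b by 0.94 ± 0.19. In the NF-kB and CD40 response 10 of 31 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 1.52e-06; adjusted p = 0.612 with an estimated correlation). Ccl22 rose by 1.97 ± 0.20, Gadd45b by 1.81 ± 0.22, the costimulator gene Cd80 by 1.45 ± 0.17 and Ebi3 by 1.34 ± 0.19. Oxidative phosphorylation had 3 of 36 higher (7 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 6.32e-05, and adjusted p = 0.617 with an estimated correlation). Cyc1, Ndufa5 and Cox5a rose by 0.87 ± 0.21, 0.72 ± 0.19 and 0.68 ± 0.18.

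**Figure D3:**
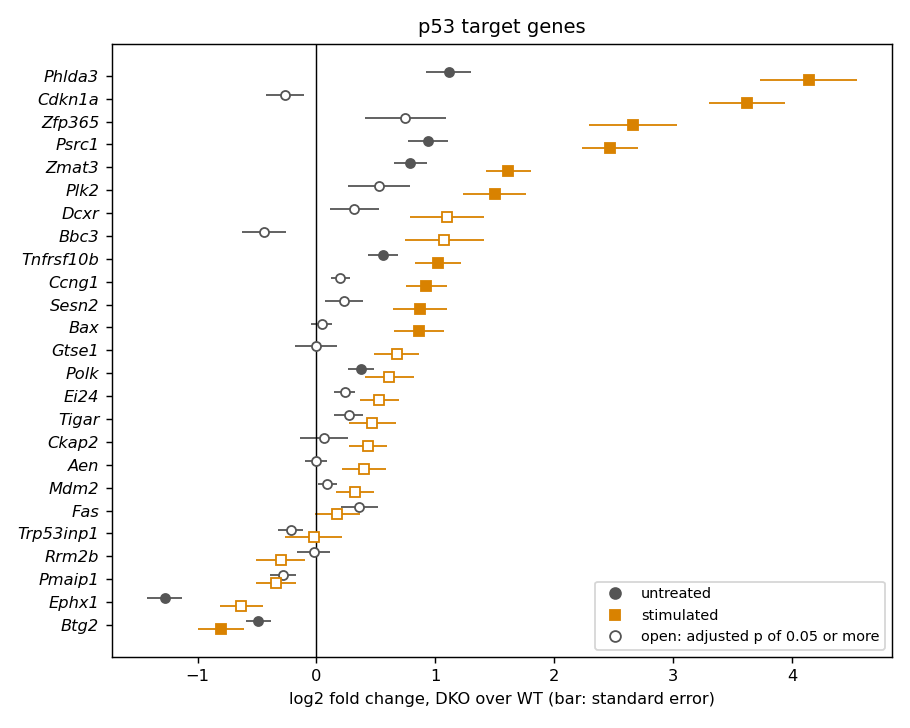
Log2 fold changes, DKO over WT, of the 25 tested p53 targets in untreated (grey) and stimulated (orange) cells, with standard errors from the F statistic as bars; filled points have an adjusted p under 0.05. In stimulated cells 10 of the 25 were higher and 1 lower, with Phlda3 and Cdkn1a highest at 4.14 and 3.62, and in untreated cells 5 were higher and 2 lower.

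Immediate early genes had 5 of 23 higher and 2 lower (6 and 3 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.0119, and adjusted p = 0.612 with an estimated correlation). Jun stood at 1.66 ± 0.21 and Nr4a1 at 1.32 ± 0.19. Glycolysis and hypoxia had 2 of 25 higher and 1 lower (3 and 2 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00827, and adjusted p = 0.612 with an estimated correlation). Gpi1 stood at 0.78 ± 0.19, the lactate transporter gene Slc16a1 at 0.72 ± 0.19 and the glucose transporter gene Slc2a3 at -0.69 ± 0.18. No single gene of DNA replication passed, over all genes or adjusted over the list alone, while the median of 34 genes was 0.38 (camera adjusted p = 0.000339, and adjusted p = 0.612 with an estimated correlation). Dendritic cell genes had 1 of 5 higher, Flt3 with 0.91 ± 0.20 (3 adjusted over the list alone), and a median of 0.64 (camera adjusted p = 0.0368, and adjusted p = 0.612 with an estimated correlation).

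Among the lists that were lower in stimulated DKO cells, B cell receptor signalling had 6 of 30 genes lower (8 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.000769, and adjusted p = 0.612 with an estimated correlation). Bank1 changed by -1.14 ± 0.19 and Fcgr2b by -0.88 ± 0.16. Antigen presentation had 7 of 21 lower and 1 higher (9 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.000430, and adjusted p = 0.612 with an estimated correlation). H2-Ob changed by -1.10 ± 0.17, Ciita by -0.92 ± 0.17 and Ifi30, on the higher side, by 1.09 ± 0.19. Follicular B cell genes had 3 of 15 lower and 1 higher (7 and 2 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.0247, and adjusted p = 0.612 with an estimated correlation). The transcription factor gene Bach2 changed by -0.92 ± 0.24. Marginal zone genes had 3 of 16 lower and 1 higher (3 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.0488, and adjusted p = 0.612 with an estimated correlation). Myof changed by -1.65 ± 0.30, Cd1d1 by -0.93 ± 0.17 and the Notch target gene Hes1 by 2.02 ± 0.50. Cholesterol synthesis had 2 of 20 lower, Hmgcs1 with -0.88 ± 0.20 and Sc5d with -0.67 ± 0.17 (2 adjusted over the list alone), and a median of -0.40 (camera adjusted p = 0.00227, and adjusted p = 0.612 with an estimated correlation). Interferon-stimulated genes had 5 of 34 lower (5 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.0206, and adjusted p = 0.770 with an estimated correlation). Ifi203 changed by -1.03 ± 0.18 and Stat2, which carries the interferon signal, by -0.97 ± 0.19.

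In stimulated cells, too, some calls were lost on leaving out 1 library. Without WT number 1 the calls for immediate early genes (camera adjusted p = 0.0627), glycolysis (0.161), cholesterol synthesis (0.134), interferon-stimulated genes (0.843, turned up) and dendritic cell genes (0.159) were lost. Without the unnumbered WT library the call for follicular genes was lost (camera adjusted p = 0.120), and without DKO number 1 those for immediate early genes (0.142) and dendritic cell genes (0.193). Without DKO number 2 those for marginal zone genes (camera adjusted p = 0.123), interferon-stimulated genes (0.505, turned up), antigen presentation (0.123) and dendritic cell genes (0.124) were lost. Of the 84 genes named for stimulated cells, 44 lost the call on leaving out 1 library, among them all 3 called genes of oxidative phosphorylation. They were Adgre1, Bach2, Bank1, Basp1, Bcl2l11, Cd1d1, Cd24a, Chac1, Ciita, Cox5a, Cxcr3, Cyc1, Ell2, Fcgr2b, Flt3, Gpi1, H2-Ob, Hes1, Hmgcs1, Hnrnpab, Ifi203, Ifi208, Ifi30, Ighg1, Il2rb, Mrc1, Myc, Ndufa5, Nop56, Pecam1, Plxnb2, Polr1b, Polr1c, Pspc1, Rps20, Rps27, Sc5d, Slamf7, Slc16a1, Slc2a3, Stat2, Tcf7, Xbp1 and Zfp385a. The losses were 36 without WT number 1, 41 without the unnumbered WT library, 1 without DKO number 1 and 0 without DKO number 2.

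The other 15 tested lists did not pass camera in stimulated cells, and the camera adjusted p closes each bracket that follows. Among the other hnRNP genes 2 of 26 rose, Hnrnpll by 2.55 ± 0.26 (edgeR adjusted p = 0.00157) and Hnrnpab by 0.76 ± 0.20 (1 adjusted over the list alone, 0.391). The median of that list was -0.02, its mean 0.11 and the camera direction up. Germinal centre genes had 2 of 18 higher and 1 lower (2 and 1 adjusted over the list alone, 0.994). The semaphorin receptor gene Plxnb2 stood at 1.16 ± 0.18, Basp1 at 1.06 ± 0.23 and Cd38 at -1.51 ± 0.19. Plasma cell genes had 3 of 15 lower (4 adjusted over the list alone, 0.178). These were Ell2 (-0.94 ± 0.18), Slamf7 (-0.93 ± 0.17) and Xbp1 (-0.78 ± 0.18). B1 and age-associated genes had 3 of 15 higher and 3 lower (3 and 5 adjusted over the list alone, 0.772). The chemokine receptor gene Cxcr3 stood at 2.14 ± 0.48, Cd5 at -1.43 ± 0.24 and Spn at -1.26 ± 0.19. Transitional B cell genes had 2 of 9 lower, Ms4a4c with -1.16 ± 0.21 and Cd24a with -0.89 ± 0.18 (2 adjusted over the list alone, 0.178). Homing and cytokine receptors had 3 of 26 higher and 5 lower (3 and 7 adjusted over the list alone, 0.391). Tnfrsf8, which encodes CD30, stood at 3.20 ± 0.27 and the interferon receptor gene Ifngr1 at -1.11 ± 0.17. Apoptosis regulators had 3 of 22 higher and 3 lower (4 and 6 adjusted over the list alone, 0.391). Bmf stood at -1.31 ± 0.19 and Bcl2l11 at -0.87 ± 0.17. The unfolded protein response had 2 of 26 lower, with Chac1 at -1.85 ± 0.45 (2 adjusted over the list alone, 0.0779). SR proteins had 1 of 29 higher, Pspc1 with 0.87 ± 0.19 (1 adjusted over the list alone, 0.178), and mitosis none of 32 past the threshold, also adjusted over the list alone (0.391). Of the immunoglobulin constant genes Ighg1 rose by 0.87 ± 0.18 and the other 11 did not pass (1 adjusted over the list alone, 0.662). The median of that list was -0.17, its mean 0.19 and the camera direction up.

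For other cell types, T cell genes in stimulated cells had 1 of 10 higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.974). Tcf7 stood at 1.16 ± 0.20 and Cd2 at -1.45 ± 0.29, and the median of the list was 0.07, its mean -0.03 and the camera direction down. Monocyte genes had 2 of 11 lower, Mrc1 with -2.00 ± 0.55 and Adgre1 with -0.69 ± 0.18 (3 adjusted over the list alone, camera adjusted p = 0.271). None of 5 erythroid genes (camera adjusted p = 0.391) and none of 5 histone genes (camera adjusted p = 0.190) passed, against 0 and 2 adjusted over the list alone. With under 5 tested genes, Il2rb (-1.03 ± 0.28) fell among 3 natural killer cell genes (2 adjusted over the list alone), Gp1ba (2.25 ± 0.45) rose among 2 platelet genes and Pecam1 (-1.08 ± 0.18) fell among 3 stromal genes, the last 2 lists with the same numbers adjusted over the list alone.

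Meiosin had no count in either stimulated WT library and 24.8 ± 5.78 CPM in stimulated DKO cells, at least 305-fold higher against a floor of 3 counts over the WT group, which covers counting error only. Nfe2 rose from 4 and 2 counts to 4140 and 2421 (10.05 ± 0.36, edgeR adjusted p = 4.70e-06), Stag3 from 2.51 to 72.7 CPM (4.85 ± 0.23) and the protease inhibitor gene Serpine2 from 0.502 to 14.2 CPM (4.81 ± 0.34). Also higher were a copy of the 7SK noncoding RNA, whose reads other copies can share, with 4.15 ± 0.47, the ephrin receptor gene Epha2 with 3.99 ± 0.40, Mt2 with 3.45 ± 0.42 and Lrrc32, which holds latent TGF-beta at the cell surface, with 3.35 ± 0.44. Among the genes that fell were Tenm4 (-3.35 ± 0.50), Synj2 (-2.83 ± 0.59, from 55.1 ± 50.5 to 7.80 ± 1.85 CPM, and -1.32 without the unnumbered WT library), Nxpe2 (-2.78 ± 0.17, from 115 to 16.9 CPM), Hapln1 (-2.45 ± 0.36), Cd276 (-2.41 ± 0.54, and -1.77 without DKO number 2), Dhtkd1 (-2.39 ± 0.32), the interferon-activated gene Ifi211 (-2.36 ± 0.33) and the myosin gene Myo1f (-2.36 ± 0.20). Ifi208 was also lower (-2.60 ± 0.61, edgeR adjusted p = 0.0313), a call lost without the unnumbered WT library. Of the 6 genes tested within 100 kb of Hnrnpa1, Zfp385a was the only one besides Nfe2 past the threshold (-0.71 ± 0.19).

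The number of genes past the threshold was 743 without WT number 1, 576 without the unnumbered WT library, 3481 without DKO number 1 and 5977 without DKO number 2, each of which leaves a lone library assumed to vary like the other group. With no filter on low counts 2847 genes passed, and a single fit over the 10 libraries of the 4 groups gave 3429, of which 56.0% were higher against 45.2% of the 1625.

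**Figure D4:**
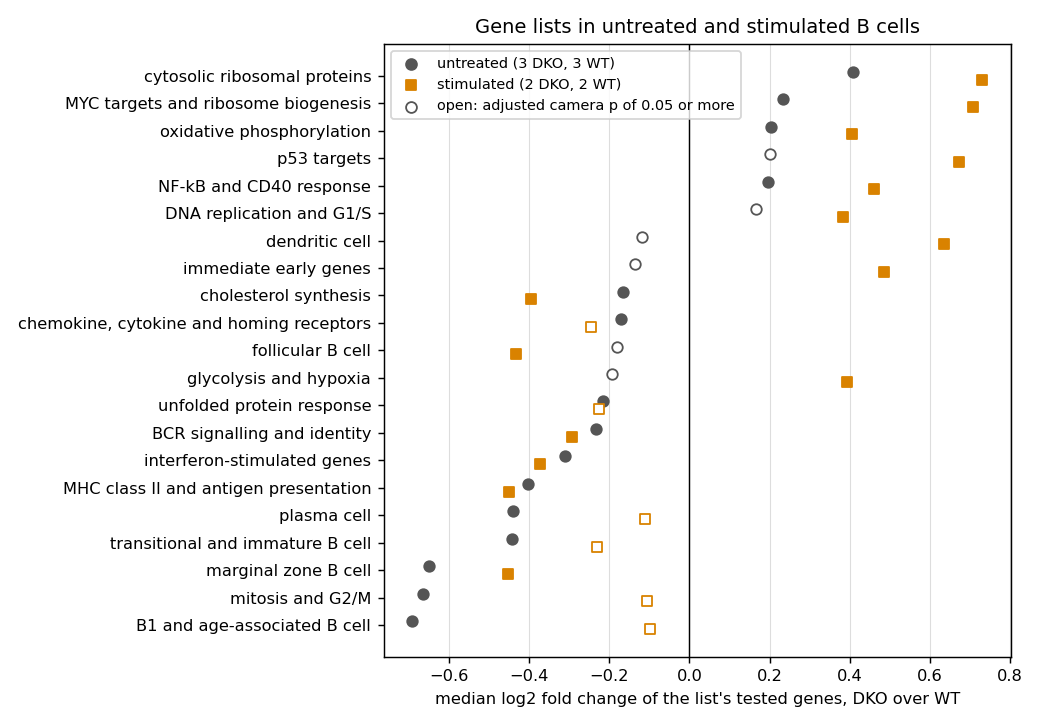
Median log2 fold change, DKO over WT, of the tested genes of each list that passed camera in untreated or in stimulated cells; grey circles are untreated and orange squares stimulated cells, and filled points have a camera adjusted p under 0.05. Ribosomal proteins stand at 0.41 and 0.73 and B cell receptor genes at -0.23 and -0.29.

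Both comparisons pointed largely the same way, gene by gene. They share no library, but the labels do not say whether they share animals. Of 13068 genes tested in both, 361 were higher in both, where independent lists of 1177 and 656 genes would share 59.1, and 532 were lower in both, where lists of 1421 and 833 would share 90.6. A single gene was called in opposite directions, where 146 would be by the same reckoning. That reckoning takes every tested gene as equally likely to be called. Among genes changed by at least 1 on the log2 scale, 89 were higher in both (4.14 for independent lists), 175 lower in both (14.5) and none opposite. Without that minimum change, Nfe2, Meiosin, Stag3, Mt2, Phlda3, Ccl22 and Hnrnpll were among the genes higher in both. Cd2, Cd38, Bmf, Pecam1, Bank1 and Fcgr2b were among those lower in both. Mt2 and Hnrnpll turned sign in untreated cells when the additional WT libraries counted as WT. Across the 13068 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.651 and Spearman's rho 0.639.

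The interaction asked whether the genotype effect itself differed between stimulated and untreated cells. For Cdkn1a it did. WT cells had 47.4 ± 5.64 CPM untreated and 1.82 ± 0.55 after stimulation, while DKO cells had 39.7 ± 9.19 and 23.3 ± 8.37. The interaction was 3.93 ± 0.38 on the log2 scale (edgeR adjusted p = 0.00250). Tnfrsf8 followed the same course, with 15.7 and 2.12 CPM in WT and 22.2 and 20.1 in DKO cells (2.74 ± 0.31). Lrrc32 had 4.43 and 0.549 CPM in WT and 3.05 and 5.88 in DKO cells (3.94 ± 0.51), and Phlda3 had an interaction of 3.07 ± 0.46. Col27a1, a collagen gene (2.99 ± 0.39), and Serpine2 (3.19 ± 0.49) were also relatively higher in stimulated DKO cells, and Nlrc3, a negative regulator of innate signalling, was lower (-1.51 ± 0.25), with 20.5 CPM in stimulated WT and 5.13 in stimulated DKO cells. In all, 21 of 15006 tested genes passed an adjusted p of 0.05, 20 with a positive and 1 with a negative interaction, and 1802 had an unadjusted p under 0.05. The split was less one-sided in other fits. DESeq2 called 164, with 116 positive and 48 negative. Without untreated DKO number 1 there were 72 calls, 50 positive and 22 negative.

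Of the gene lists, 12 of 31 passed camera for the interaction and none with an estimated correlation. Targets of p53 had the largest median, 0.68 (camera adjusted p = 1.54e-12; adjusted p = 0.132 with an estimated correlation), with 2 of 25 genes past the threshold, Cdkn1a and Phlda3, and 9 adjusted over the list alone. Psrc1 stood at 1.57 ± 0.30 (edgeR adjusted p = 0.0597) and Ccng1 at 0.76 ± 0.15 (edgeR adjusted p = 0.0843). The NF-kB and CD40 response had a median of 0.23 (camera adjusted p = 0.000130; adjusted p = 0.559 with an estimated correlation) with Gadd45b past the threshold at 1.59 ± 0.24 (6 adjusted over the list alone). The B1 and age-associated list had a median of 0.43 (camera adjusted p = 0.00196; adjusted p = 0.559 with an estimated correlation) with Ctla4 at 2.27 ± 0.36 (3 adjusted over the list alone). No single gene passed in the other 9 lists. MYC targets had a median of 0.47 (camera adjusted p = 5.75e-11, and adjusted p = 0.630 with an estimated correlation), with 12 genes higher adjusted over the list alone. Immediate early genes had 0.55 (camera adjusted p = 1.08e-05, and adjusted p = 0.586 with an estimated correlation), with 9 higher and 1 lower adjusted over the list alone. DNA replication had 0.28 (camera adjusted p = 0.00818, and adjusted p = 0.789 with an estimated correlation), with 1 higher adjusted over the list alone. No gene of the remaining 6 lists passed adjusted over the list alone. These were oxidative phosphorylation (0.26, camera adjusted p = 0.00534, and adjusted p = 0.767 with an estimated correlation), ribosomal proteins (0.37, 2.67e-07), mitosis (0.52, 1.44e-05), glycolysis and hypoxia (0.63, 2.84e-05), cholesterol synthesis (-0.17, 0.00196) and SR proteins (-0.18, 0.0258). The last 5 of them had adjusted p = 0.736 with an estimated correlation. Values of ribosomal protein genes and their pseudogenes differed between untreated and stimulated WT libraries, as given below. Whether the interaction cancels this was not tested.

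The interaction calls for ribosomal proteins (camera adjusted p = 0.366), oxidative phosphorylation (0.897, turned down) and SR proteins (0.745) were lost without stimulated DKO number 1. Those for the B1 list (camera adjusted p = 0.134) and cholesterol synthesis (0.0910) were lost without stimulated DKO number 2, and that for cholesterol synthesis also without stimulated WT number 1 (0.305). The call for DNA replication was lost without untreated WT number 1 (camera adjusted p = 0.227), untreated DKO number 1 (0.504), the unnumbered WT library (0.0891) or stimulated DKO number 1 (0.0565).

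Leaving out 1 library moved the count of 21 to 7, 47 and 8 without untreated WT numbers 1, 2 and 3, to 72, 5 and 11 without untreated DKO numbers 1, 2 and 3, to 10 without stimulated WT number 1, 1 without the unnumbered WT library, 3 without stimulated DKO number 1 and 1244 without stimulated DKO number 2, and Cdkn1a alone of the genes named here as past the threshold passed in all 10 fits. With no filter on low counts 491 genes passed, and with sex as a term or in the 8 male libraries, both tried after the data were seen, 81 and 62.

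Stimulated and untreated libraries of one genotype were also compared, as background for the interaction. Mitosis genes rose in both genotypes, with all 32 past the threshold in each (32 adjusted over the list alone). The median was 1.53 in WT (camera adjusted p = 4.12e-17, and adjusted p = 0.506 with an estimated correlation) and 2.29 in DKO cells (camera adjusted p = 6.20e-31, and adjusted p = 0.526 with an estimated correlation). The cyclin gene Ccnb1 stood at 1.84 ± 0.23 and 2.80 ± 0.24 and the transcription factor gene Foxm1 at 1.71 ± 0.20 and 2.30 ± 0.20. B cell receptor genes rose in both, 14 of 30 with 1 lower in WT and 11 in DKO cells (17 with 1 lower, and 13, adjusted over the list alone). Their medians were 0.40 (camera adjusted p = 0.00163, and adjusted p = 0.639 with an estimated correlation) and 0.27 (camera adjusted p = 0.00680, and adjusted p = 0.631 with an estimated correlation). Ms4a1, which encodes CD20, stood at 1.15 ± 0.11 and 1.06 ± 0.11.

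Interferon-stimulated genes fell in both genotypes, 19 of 38 with 1 higher (20 lower in WT and 25 in DKO cells, with 1 higher in each, adjusted over the list alone). Their medians were -1.35 in WT (camera adjusted p = 0.000362, and adjusted p = 0.712 with an estimated correlation) and -1.12 in DKO cells (camera adjusted p = 1.15e-05, and adjusted p = 0.631 with an estimated correlation). Isg15 stood at -4.80 ± 0.56 and -3.65 ± 0.51. In the unfolded protein response 18 of 26 fell in WT and 12 in DKO cells, with 1 higher in each (18 and 14 lower and 1 higher in each adjusted over the list alone). The medians were -0.55 (camera adjusted p = 2.98e-05, and adjusted p = 0.277 with an estimated correlation) and -0.33 (camera adjusted p = 1.15e-05, and adjusted p = 0.155 with an estimated correlation). Chac1 stood at -3.81 ± 0.28 and -5.50 ± 0.33, and Atf4, which drives the stress response, at -1.79 ± 0.16 and -1.71 ± 0.15. Oxidative phosphorylation had 29 of 36 lower in WT and 19 in DKO cells (31 and 20 adjusted over the list alone). The medians were -0.60 (camera adjusted p = 1.36e-08, and adjusted p = 0.639 with an estimated correlation) and -0.40 (camera adjusted p = 1.15e-05, and adjusted p = 0.631 with an estimated correlation). Uqcrq, a subunit of respiratory complex III, stood at -2.61 ± 0.20 and -2.22 ± 0.20. MYC targets had 32 of 35 lower in WT and 12 in DKO cells, with 1 higher in each (the same numbers adjusted over the list alone). The medians were -0.74 (camera adjusted p = 1.80e-08, and adjusted p = 0.639 with an estimated correlation) and -0.30 (camera adjusted p = 0.0261, and adjusted p = 0.782 with an estimated correlation). Nhp2 stood at -1.39 ± 0.15 and -0.81 ± 0.14. Immediate early genes had 16 of 24 lower and 1 higher in WT and 11 lower in DKO cells (17 lower and 1 higher, and 11 lower, adjusted over the list alone). The medians were -0.98 (camera adjusted p = 8.17e-07, and adjusted p = 0.385 with an estimated correlation) and -0.40 (camera adjusted p = 0.00602, and adjusted p = 0.631 with an estimated correlation). Atf3 stood at -4.98 ± 0.32 and -3.43 ± 0.28.

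A further 6 lists passed camera in 1 genotype only, which is no test of a difference between genotypes, and of these only DNA replication passed for the interaction. In WT cells 7 of 15 follicular genes rose and 1 fell (the same numbers adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.01465, and adjusted p = 0.380 with an estimated correlation). Sesn1, a stress-response gene, stood at 1.36 ± 0.14. Marginal zone genes had 8 of 16 lower and 1 higher in WT cells (the same numbers adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.0234, and adjusted p = 0.385 with an estimated correlation) and Mzb1 at -1.45 ± 0.14. Dendritic cell genes had 4 of 8 lower and 1 higher in WT cells (6 and 2 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 0.0175, and adjusted p = 0.380 with an estimated correlation) and Cox6a2 at -10.61 ± 0.85. Under the alternatives Cox6a2 ranged from -12.85 to -9.73, so the size of its change is uncertain. In DKO cells the medians of these 3 lists were 0.40, -0.55 and -1.25 (camera adjusted p = 0.0636, 0.0763 and 0.124), and their interactions had camera adjusted p = 0.286, 0.297 and 0.0719. In DKO cells 16 of 34 DNA replication genes rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.000323, and adjusted p = 0.702 with an estimated correlation) and Clspn at 1.47 ± 0.24. Of 12 immunoglobulin constant genes 6 rose and 2 fell in DKO cells (the same numbers adjusted over the list alone), with a median of 0.76 (camera adjusted p = 0.00602, and adjusted p = 0.622 with an estimated correlation) and Ighg1 at 3.62 ± 0.20. Of 9 T cell genes 6 rose in DKO cells (6 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 0.04135, and adjusted p = 0.584 with an estimated correlation). Cd5 stood at 2.70 ± 0.37 and Lck at 1.27 ± 0.22. In WT cells the medians of DNA replication, immunoglobulin constant and T cell genes were 0.17, 0.55 and 0.53 (camera adjusted p = 0.0851, 0.0851 and 0.157), and the interactions of the last 2 had camera adjusted p = 0.145 and 0.354. In total 6097 of 15006 genes passed in WT cells (2672 higher and 3425 lower) and 4952 in DKO cells (2425 higher and 2527 lower). The former count was 3557 without the unnumbered WT library.

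Stimulation, culture and the separate tables of the untreated and stimulated libraries cannot be told apart in these contrasts, and values of ribosomal protein genes and their pseudogenes differed between the tables. Nor were the untreated cells free of activation genes, with 347 ± 97.4 CPM of Mki67 in WT (mean ± SD, n = 3), and whether they were at rest was not tested. Of the 47 ribosomal protein genes 8 had under 100 CPM in untreated WT cells and none in stimulated WT cells. Rpl5 went from 71.3 to 1548 CPM, Rps6 from 65.9 to 1561 and Rps27 from 10.6 to 223. The 323 ribosomal protein pseudogenes summed to 6418 ± 319 CPM in untreated and 1879 ± 67.6 in stimulated WT cells, and all pseudogenes took 1.45% ± 0.0502 and 0.528% ± 0.0151 of counts. The list had a median of -0.25, a mean of 0.65 and the camera direction up in WT cells (18 higher and 19 lower of 47, 18 and 22 adjusted over the list alone, camera adjusted p = 2.47e-07, and adjusted p = 0.687 with an estimated correlation). In DKO cells it had a median of 0.01 and a mean of 1.02 (20 higher and 6 lower, 21 and 6 adjusted over the list alone, camera adjusted p = 3.14e-17, and adjusted p = 0.584 with an estimated correlation).

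The 2 additional WT libraries entered none of the comparisons above, apart from the alternative in which they counted as WT. Across 12491 genes, which are not independent replicates, their rank correlation with each other was 0.990, and with the untreated WT libraries it was 0.911 to 0.937. It was 0.894 to 0.927 with the untreated DKO libraries and 0.986 to 0.995 among the untreated WT libraries. Untreated WT and DKO libraries correlated at 0.972 to 0.984. The additional libraries thus lay further from the untreated WT libraries than the DKO libraries did. They had 1155 ± 56.2 CPM of Hnrnpa1, 1966 ± 176 of Hnrnpa2b1 and 1474 ± 66.6 of Gm10052, and 10609 ± 165 CPM over the ribosomal protein pseudogenes. Of the 47 ribosomal protein genes 6 had under 100 CPM in them.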

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

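The genotype effect differed between stimulated and untreated cells for 21 genes by the interaction test, which is what marked them for a closer look. The 5 largest positive ones by the rule for naming genes were Lrrc32 (3.94), Cdkn1a (3.93), Serpine2 (3.19), Phlda3 (3.07) and Col27a1 (2.99), and the only negative one was Nlrc3 (-1.51). By camera on the interaction 12 gene lists passed as well, of which none stayed past the threshold with an estimated correlation (lowest adjusted p = 0.132 with an estimated correlation, for p53 targets) and 1 passed fry. Their median interactions were 0.68 for p53 targets, 0.63 for glycolysis and hypoxia, 0.55 for immediate early genes, 0.52 for mitosis, 0.47 for MYC targets, 0.43 for B1 and age-associated genes, 0.37 for ribosomal proteins, 0.28 for DNA replication, 0.26 for oxidative phosphorylation, 0.23 for the NF-kB and CD40 response, -0.17 for cholesterol synthesis and -0.18 for SR proteins. Of the tests below, the one on erythroid and megakaryocyte markers and the one that adds genes near both ends were written after the result was seen, and the predictions of the others were written before their values were computed.

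Near-silent genes higher in untreated DKO cells, with Nfe2 foremost, could come from reads running past the 3′ ends of expressed neighbours. Of near-silent genes with only 3′ ends of expressed genes within 10 kb 17 of 448 were called higher (3.79%), against 21 of 359 (5.85%) with only 5′ ends, an odds ratio of 0.635 (95% interval 0.309 to 1.29, Fisher's exact test, p = 0.184), with 9 of 111 (8.11%) near both and 90 of 1626 (5.54%) near neither. With the genes near both counted with the 3′ ends the odds ratio was 0.785 (95% interval 0.417 to 1.49, Fisher's exact test, p = 0.445), so the prediction for read-through over the genome, an interval above 1, was not met, while lower calls were more frequent with only 3′ ends near (odds ratio 1.87, Fisher's exact test, p = 0.0156). Red cell or platelet precursors in the DKO libraries could also carry Nfe2. The 24 markers taken from the erythroid and platelet lists, without Tfrc, summed to at most 59.3 CPM in a DKO library, while Nfe2 gained 121 CPM. The mean sum was 55.4 CPM in untreated DKO and 63.1 in untreated WT cells. Of these, Car2 alone held 48.6 and 46.7 CPM. For Nfe2 alone, whose tail lies 1.52 kb from that of the deleted Hnrnpa1, transcription through the altered locus and a change at its own promoter cannot be told apart from gene counts.

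Targets of p53 higher in stimulated DKO cells could rest on 1 library. The median interaction of the list was 0.40 without stimulated DKO number 1, its lowest value, and above that without each of the other 3. It was 0.59 among the 8 male libraries, where sex could not enter. Of 10000 random lists matched on expression, GC content and length, 0 reached the list's median of 0.67 in stimulated cells, and the middle one stood at 0.03. None of these explanations met its prediction, while the list itself had adjusted p = 0.612 with an estimated correlation in stimulated cells and 0.132 for the interaction.

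Ribosomal protein genes higher in untreated DKO cells could share a cause with other short, GC-rich and abundant transcripts. Of 10000 lists matched on these, 0 reached the list's median of 0.41. The middle one stood at 0.14, and at 0.39 against 0.73 in stimulated cells. Only the list's own genes were kept out of the draws, so other ribosomal protein genes could be among those drawn. Whether unrelated genes of like length, GC content and abundance were higher as well is thus not shown. For oxidative phosphorylation in untreated cells 192 of 10000 (1.92%) reached the median of 0.20, with the middle one at 0.11. Among the 4 male libraries the median was 0.44, and as for reads moved from pseudogenes, the pseudogenes gained 1695 CPM themselves while the list gained 13442.5 CPM. None of these explanations met its prediction as the whole cause, while the list itself had adjusted p = 0.298 with an estimated correlation.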

How the results depend on the processing

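Fits with a sex term or with male libraries alone, and list tests with the additional WT libraries, were chosen after seeing the data, and the other alternatives were fixed beforehand. The untreated count of 2638 genes stayed within 1.5 times under RLE scaling, DESeq2, either filter and the removal of immunoglobulin genes. It was 623 with a log2 fold change of at least 1, 319 with both additional WT libraries added, 4392 with the sex term and between 923 (without WT number 3) and 2779 (without WT number 2) on leaving out 1 library. With the additional libraries added, 32 of 92 named genes kept direction and call, 55 lost the call and 5 turned sign: Mt2 (-0.91), Mvk (0.0779), Hmgcs1 (0.0921), Hnrnpll (-0.0007) and Cbx5 (-0.43). Among the 55 were Rplp2 (0.03), Polr1c (0.09), Zmat3 (0.14), Ebi3 (0.19) and Gh (1.25). Of the 15 gene lists 9 kept the call there, and it was lost for NF-kB and CD40 (camera adjusted p = 0.185), antigen presentation (0.129), the unfolded protein response (0.812), homing receptors (0.0815), interferon-stimulated genes (0.354, turned up) and cholesterol synthesis (0.0638, turned up). The cause was not tested, and the fit with the additional libraries had no term for their separate table. Of 10 ways to split the 6 untreated libraries into groups of 3, which are too few for a share under 0.05, 1 gave 2638 genes and the highest other gave 0. The stimulated count of 1625 was 2847 with no filter, 895 with a log2 fold change of at least 1, 3429 in 1 fit over 10 libraries and between 576 (without the unnumbered WT library) and 5977 (without DKO number 2). The interaction count of 21 was 164 with DESeq2 (70.7% higher), 491 with no filter (72.1% higher), 81 with the sex term, 62 in the 8 male libraries and between 1 (without the unnumbered WT library) and 1244 (without stimulated DKO number 2), against 95.2% higher in the fit reported. On leaving out 1 library the term for the targeted genes ranged from -0.47 to 0.30 (Hnrnpa1, -0.51 in the 8 male libraries) and from -0.30 to 0.19 (Hnrnpa2b1), highest without untreated DKO number 2 and never past the threshold. The counts for stimulated against untreated cells were 2620 in WT and 2318 in DKO cells with a log2 fold change of at least 1, and between 3557 (without the unnumbered WT library) and 7031 (without stimulated DKO number 2) in WT cells on leaving out 1 library. The cause of these moves was not tested, except that a minimum fold change removes genes by its construction. The stimulated DKO libraries differed from each other more than any other replicate pair (chi-square per degree of freedom 49.5, against 9.66 for the stimulated WT pair).

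With the replicate number as a block, the counts were 786 in untreated cells, 3 for the interaction and 2957 for stimulated against untreated DKO cells, and the list call for cholesterol synthesis in untreated cells was lost (camera adjusted p = 0.0571). Deviations of same-numbered untreated libraries correlated at -0.353, -0.351 and 0.139, and not every library correlated best with its own number. These values gave no sign of pairing. They cannot exclude it, since WT and DKO libraries of numbers 1 and 2 also differed in sex. For DKO against WT in stimulated cells no paired analysis was possible because the columns of these groups share only 1 number.

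Of 15 gene lists past camera in untreated, 15 in stimulated cells and 12 for the interaction, 0, 0 and 0 remained with an estimated correlation, and 8, 1 and 1 were among the 9, 4 and 1 that passed fry. The overlap of 893 genes called in the same direction was 264 with a log2 fold change of at least 1. Of 93 named genes in untreated cells, 1393 of 1579 values under the alternatives kept direction and call and 181 lost the call, and of 84 in stimulated cells 814 of 923 kept both and 109 lost the call. For 13 named genes of the interaction 185 of 247 values kept both, 48 lost the call, 12 gained a call and 2 turned sign. Depth limits near-silent genes, where Nfe2 and Meiosin have under 10 counts in the WT libraries of the 4 groups and their fold changes rest on those. The standard errors printed for these genes may be too small.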

Other observations

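Genes of B cell activation, chosen after their values were seen, were present in the untreated libraries. Per the labels, RNA of these cells was extracted after isolation and a wash, with no culture named, and whether they were activated by then was not tested. Ki-67 (Mki67), a marker of dividing cells, had 347 ± 97.4 CPM in untreated WT, 198 ± 70.9 in untreated DKO, 1622 ± 51.1 in stimulated WT and 1159 ± 588 in stimulated DKO cells (mean ± SD, n = 3, 3, 2 and 2). Ccl22, a chemokine gene of activated B cells, had 577 ± 136, 1888 ± 469, 1842 ± 54.1 and 6719 ± 184 CPM in the same order. Il2ra had 226 ± 8.66, 153 ± 37.8, 136 ± 12.8 and 84.4 ± 5.97 CPM, and Cd83, which rises early on activation, 529 ± 21.2, 517 ± 59.0, 648 ± 37.1 and 565 ± 43.1.

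Xist, which is expressed in females, had 2117 CPM in untreated WT number 2 and 2004 in untreated DKO number 1, where Ddx3y of the Y chromosome had 0 and 0.0632, and the other 8 libraries of the 4 groups read as male. The deviations of these libraries from their group means correlated at 0.440.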
